A study of Rattus norvegicus with 6 samples.

How the data were processed

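RNA abundance was measured by sequencing in primary bone marrow mesenchymal stem cells from rat femur, with 3 libraries of cells given 3% cigarette smoke extract (CSE) for 6 h and 3 libraries of control cells. The deposited table holds raw read counts for 37209 gene symbols in 6 columns, 1 per library, as whole numbers of at least 0 with no normalization. Per the submitters' processing notes, HISAT2 2.0.4 and the rat genome build Rnor_6.0 were used, with no role given for either. The counting tool, the strand setting and the annotation release are not given in the sources used here. Without a stated strand setting, reads of overlapping or antisense genes cannot be told apart, and genes with near-identical copies may have had reads split or dropped between them. This applies to the ferritin genes Fth1 and Ftl1, Hspa1a and Hspa1b, Hspa8, Gapdh, the granzyme B family and the ribosomal protein genes, whose levels are uncertain for that reason.

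Each column was assigned to its group and replicate by its name, which matches 1 sample title. No genome sequence was used. A RefSeq gene table of the rat assembly GRCr8, which is not the build named in the notes, served only to check symbols and to assign genes to chromosomes. Of the symbols in the count table, 20212 matched a current symbol in that table, 2844 a synonym, 4492 a numeric gene identifier, and 9661 none. Members of the fixed gene lists that the count table names by an older symbol were looked up under that symbol. Of 574 named protein-coding genes that the RefSeq table assigns to chromosome X, 563 were listed at 0 in all 6 libraries, so chromosome X is almost absent from the counts and its genes are reported only as listed at 0.

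Library totals ranged from 15958621 to 22589327 counts, so that 3 counts, taken as the upper limit that a count of 0 allows, corresponded to between 0.142 and 0.177 counts per 1000000 counts (CPM) of the TMM-scaled library size. Such limits, and the 95% exact interval given for a ratio that rests on 3 control counts, cover counting error only. Genes were filtered with filterByExpr of edgeR 4.0.16 in R 4.3.3, which kept 13390 genes of the 21252 with any count. Library sizes were scaled with TMM factors, which averaged 0.937 in the CSE libraries and 1.07 in the control libraries, and normalized CPM values are given as mean ± SD over 3 libraries. CSE was compared with control by edgeR's quasi-likelihood F test, 2-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of F. Replicates of a group were compared by a chi-square test of their counts over genes. The chi-square per degree of freedom lay between 3.35 and 6.00 within groups and between 191 and 234 across groups, so no pair of libraries agreed within sampling noise. Each library was counted as 1 replicate, although this test cannot tell separate cultures from repeat libraries of 1 culture.

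Before the data were examined, 39 gene lists were fixed from general knowledge of the tissue and the exposure. They cover oxidant, xenobiotic, metal, heat shock and unfolded protein responses, ferroptosis and iron handling, autophagy and lysosome, p53, cell cycle and senescence, early response and serum-responsive genes, inflammation and interferon, skeletal and fat lineage genes, BMP, WNT and TGF-beta signalling, matrix, energy metabolism, translation, and markers of other cell types in bone marrow. The 38 lists with 5 or more tested members were tested with camera of limma 3.58.1, with a preset inter-gene correlation of 0.01 and adjustment over the lists. Member counts were also adjusted over the list alone. They equalled the counts over all genes except in the 6 lists where both are given. The rule for named genes, also fixed before the data were examined, took the title genes and their partners, the 10 largest changes in each direction, and up to 4 members per list. The title genes and partners are Ncoa4, Fth1, Ftl1, Tfrc, Slc40a1, Gpx4, Slc7a11, Hmox1, Acsl4 and Nfe2l2. The 10 largest changes were drawn from called genes with a mean CPM of 5 or more, a gene symbol, and every CSE library on the same side of every control library. List members were taken by smallest adjusted p. Some genes that the rule takes are not named. Genes named outside this rule are marked as chosen after their values were seen. Library totals and composition were compared by exact 2-sided permutation tests, which cannot give a p below 0.1 with 3 libraries against 3.

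The fitting steps were tested on simulated counts drawn from the mean expression, dispersion and library sizes of the real data. In the simulated comparison of CSE with control, over 13197 genes, 52% of 50 genes changed 1.25-fold were recovered, 80% of 50 changed 1.5-fold, 84% of 50 changed 2-fold and 92% of 50 changed 4-fold. A further 30 genes were raised 1.5-fold together as a list. After the filter on low counts, 225 changed genes were in the fit, and changed genes lost to the filter count as not recovered. Of 12972 unchanged genes, 13 were called, which made 6.95% of 187 calls. Few genes were changed in the simulation, whereas 9894 of 13390 were called in the real data. The simulation therefore does not test the scaling in a setting where most genes differ. Alternatives covered other scaling factors, other filters on low counts, DESeq2 1.42.0, limma-voom with and without quality weights, a robust fit, a replicate block, each library left out in turn, an estimated correlation for the lists, fry (which asks whether a list moves on balance in 1 direction and does not compare it with other genes), and a test against a 2-fold change. Chosen after seeing the data were a run with all libraries thinned to the smallest total and a run without the mitochondrially encoded genes.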

Results

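Primary mesenchymal stem cells of rat femoral bone marrow (BMSCs), stromal progenitors that can form bone, cartilage and fat cells, were exposed for 6 h to 3% cigarette smoke extract (CSE), a medium through which cigarette smoke has been drawn, or kept in serum-free medium as the control. Whether the extract was diluted in serum-free medium is not given in the sources used here. RNA was sequenced from 3 libraries per group. The title of the study names ferritinophagy, the delivery of the iron store ferritin to the lysosome by autophagy, and skeletal development, so the comparison asks which genes of iron handling, autophagy and skeletal lineages differ between exposed and unexposed cells. The labels do not say whether the 3 libraries of a group came from separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical. The CSE libraries held 22589327, 19433637 and 20768692 counts and the control libraries 15958621, 17682585 and 18651194. Totals averaged 20930552 ± 1584059 with CSE and 17430800 ± 1363831 in the control (SD, n = 3, exact permutation p = 0.1, the smallest this design allows). More genes had a count with CSE, 17865 ± 113 against 17183 ± 238 (SD, n = 3, exact permutation p = 0.1), and with all libraries thinned to 15958621 counts the ranges remained apart, 17348 to 17565 against 16925 to 17167. The first principal component held 88.6% of the variance and separated the groups. Values below are normalized counts per 1000000 counts (CPM, mean ± SD, n = 3) and log2 fold changes of CSE over control ± SE, with adjusted p from edgeR's quasi-likelihood test.

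Most tested genes differed between the CSE and control libraries at 6 h. The largest rises included Cyp1a1, which oxidises polycyclic aromatic hydrocarbons, the stress cytokine gene Gdf15, the haem-degrading enzyme gene Hmox1 and the heat-inducible Zfand2a, while the endothelin gene Edn1 and the osteoblast transcription factor gene Sp7 were among the largest falls. Of 13390 genes tested, 9894 (73.9%) passed the threshold, 4867 higher and 5027 lower. At least 2-fold changes were seen in 1438 genes upward and 1932 downward. In 10143 genes (75.8%) every CSE library lay on the same side of every control library, against 10% by chance. The median log2 fold change was −0.02 with TMM scaling. Scaling by total counts alone moved it by −0.19 and upper-quartile scaling by −0.14. The share of higher genes among those called was 49.2%, or 37.2% under total counts alone, and among those called with a 2-fold change it was 42.7%, or 30.7%.

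**Figure D1:**
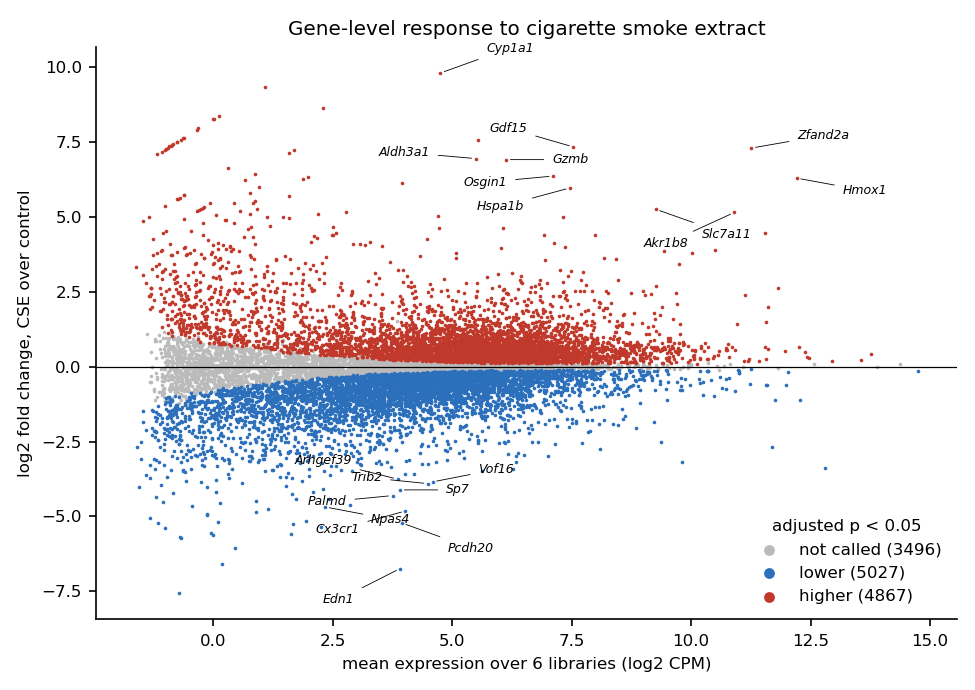
Log2 fold change of CSE over control (y axis) against mean expression over 6 libraries in log2 CPM (x axis), with 1 point per tested gene, red for the 4867 called higher, blue for the 5027 called lower and grey for the rest. Most of the 10 largest changes in each direction by the fixed rule are named, and the fitted values of the 20 genes with no control count and the 1 with no CSE count depend on the prior count of the fit.

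Among the 10 largest rises, Cyp1a1 averaged 53.9 ± 0.874 CPM with CSE and had 3 counts in all control libraries together, a ratio of 1001 with a 95% counting interval of 342 to 4856. Aldh3a1, an aldehyde dehydrogenase gene, rose 123-fold to 89.2 ± 1.40 CPM from 0.725 ± 0.164. Gdf15 rose 161-fold, from 2.30 ± 0.451 to 368.6 ± 42.4 CPM, and Zfand2a 157-fold, from 31.0 ± 1.88 to 4882 ± 337 CPM. Gzmb, the gene of the cytotoxic granule protease granzyme B, rose 120-fold, from 1.16 ± 0.316 to 138.9 ± 8.62 CPM. Osgin1, an oxidative stress-induced gene, rose 82.2-fold and the inducible HSP70 gene Hspa1b 62.6-fold. The aldo-keto reductase gene Akr1b8 rose 35.4-fold to 3728 ± 172 CPM. Among the 10 largest falls, Edn1 dropped from 29.8 ± 1.81 to 0.269 ± 0.0916 CPM, with a log2 fold change of −6.74 ± 0.17. The protocadherin gene Pcdh20 was at −5.22 ± 0.17, the chemokine receptor gene Cx3cr1 at −4.82 ± 0.13, and the neuronal activity-regulated transcription factor gene Npas4 at −4.69 ± 0.22. Palmd, Sp7, the pseudokinase gene Trib2, Vof16 and Arhgef39 followed at −4.31, −4.12, −3.91, −3.85 and −3.76. Cx3cr1 is expressed by monocytes and macrophages, and of 19 macrophage markers tested 5 rose, 6 fell and 8 did not pass. The edgeR adjusted p of each gene named in this paragraph was at or below 3.4e-12, the value of Npas4.

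Both ferritin genes, the iron import gene Tfrc and the iron export gene Slc40a1 were higher with CSE, whereas the ferritinophagy receptor gene Ncoa4 was nearly level. Fth1, the ferritin heavy chain gene, rose 6.14-fold from 1012 ± 22.6 to 6209 ± 186 CPM, and the light chain gene Ftl1 rose 2.83-fold from 1578 ± 404 to 4469 ± 633 CPM. The transferrin receptor gene Tfrc rose 2.35-fold from 86.4 ± 1.24 to 203 ± 9.21 CPM, and the iron exporter gene Slc40a1 rose 5.53-fold from 2.26 ± 0.689 to 12.7 ± 0.920 CPM. Hmox1 rose 78.4-fold, from 119 ± 7.75 to 9348 ± 357 CPM. Ncoa4 had 156 ± 3.70 CPM with CSE and 136 ± 6.36 in the control, a log2 fold change of 0.19 ± 0.05 (edgeR adjusted p = 0.0020, every CSE library above every control library). Its call did not hold under upper-quartile scaling (0.06, edgeR adjusted p = 0.297) or total counts alone (0.01, edgeR adjusted p = 0.922), within a range of adjusted p from 2.9e-04 to 0.922 over all alternatives. Of 24 tested genes of iron uptake, storage and export, 12 rose, 7 fell and 5 did not pass, with a median log2 fold change of 0.20 (camera adjusted p = 0.0015, and adjusted p = 0.0586 with an estimated correlation). That median was 0.01 under total counts alone, and the call of this list also ended with limma-voom (adjusted p = 0.122, the highest of a range from 8.7e-07 over all alternatives).

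**Figure D2:**
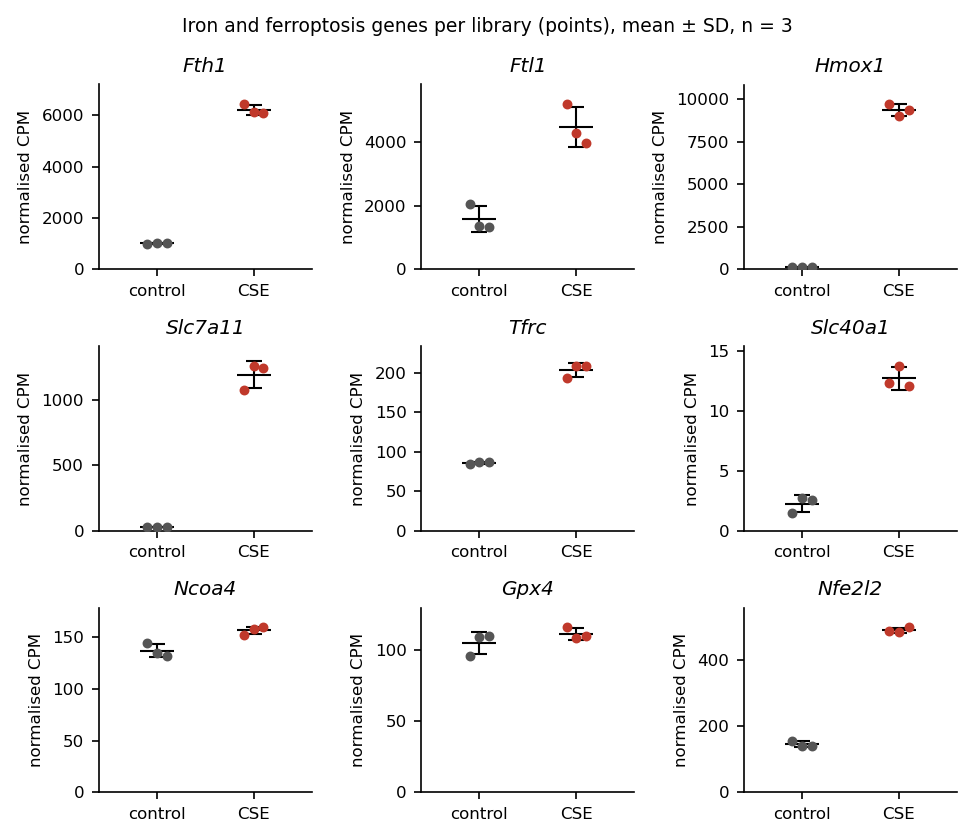
Normalized CPM (y axis) of 9 iron and ferroptosis genes in the 3 control and 3 CSE libraries (points, 1 per library), with the mean and SD of each group as bars. Fth1 averaged 1012 in the control and 6209 with CSE, whereas Ncoa4 averaged 136 and 156, and Gpx4 averaged 105 and 111 without passing the test.

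The cystine importer gene Slc7a11, which supplies glutathione synthesis and restrains ferroptosis, rose 38.2-fold from 31.3 ± 0.839 to 1193 ± 103 CPM. Gpx4, the gene of the peroxidase that reduces lipid hydroperoxides, had 111 ± 4.04 CPM with CSE and 105 ± 7.84 in the control, and its log2 fold change of 0.08 ± 0.06 did not pass (edgeR adjusted p = 0.195). Its sign turned under upper-quartile scaling (−0.05) and total counts alone (−0.10). Acsl4, a ferroptosis driver gene on chromosome X, was listed at 0 in all 6 libraries, as were 563 of 574 named protein-coding genes that the RefSeq table of GRCr8 assigns to that chromosome. Of 21 tested ferroptosis suppressors 13 rose, 5 fell and 3 did not pass, with a median of 0.94 (camera adjusted p = 1.1e-09). Hspb1, a small heat shock protein gene, rose 14.8-fold and Gclc, the catalytic subunit of glutamate-cysteine ligase, 5.25-fold. Scd, the stearoyl-CoA desaturase gene, fell by 1.78. The other falls, named after their values were seen, were Dhodh (−1.29 ± 0.14), Mboat1 (−1.28 ± 0.07), Fancd2 (−0.88 ± 0.08) and Aifm2 (−0.77 ± 0.07). Among the suppressors that rose, Slc7a11, Gclc, Gclm, Fth1 and Ftl1 are also in the list of NRF2 targets, and Hspb1 is in the heat shock list. The calls of these lists are therefore not independent. Of 17 tested ferroptosis drivers and markers 12 rose, 3 fell and 2 did not pass, with a median of 0.31 (camera adjusted p = 0.0204, and adjusted p = 0.111 with an estimated correlation). The members of this list with the smallest p were Bach1 (2.32 ± 0.07), which represses Hmox1 and the ferritin genes, Tfrc, the P450 reductase gene Por (1.10 ± 0.06) and the NRF2 inhibitor gene Keap1 (1.20 ± 0.07).

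Targets of NRF2, the transcription factor of the oxidant response, rose almost without exception. Of 29 tested, 27 rose, none fell and 2 did not pass, with a median of 2.10 (camera adjusted p = 1.4e-71, and adjusted p = 0.0279 with an estimated correlation). Beside Hmox1, Slc7a11 and Akr1b8, the autophagy receptor gene Sqstm1 rose from 260.2 ± 4.54 to 5715 ± 292 CPM, and Nfe2l2, the NRF2 gene itself, rose 3.37-fold from 146 ± 9.38 to 490.0 ± 8.15 CPM. Of 9 tested genes of the aryl hydrocarbon receptor battery, 7 rose and 2 did not pass, with a median of 0.88 (camera adjusted p = 1.0e-12). The quinone reductase gene Nqo1 rose 5.22-fold and the ADP-ribosyltransferase gene Tiparp 9.09-fold. The glutathione list was divided, with 17 of 29 higher, 7 lower and 5 not past the test, and a median of 0.31 (camera adjusted p = 6.8e-06). Its synthesis and reduction genes Gclc, Gclm (2.90 ± 0.06) and Gsr (2.82 ± 0.05) rose. The metallothionein genes Mt1a and Mt2A rose as well, by log2 fold changes of 4.17 ± 0.28 and 4.05 ± 0.17, with the zinc exporter gene Slc30a1 at 1.68 ± 0.07. Of 7 tested metal response genes 6 were higher and 1 did not pass (median 1.68, camera adjusted p = 7.4e-09).

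All 22 tested genes of the cytosolic heat shock list rose, with a median of 2.32 (camera adjusted p = 2.3e-42, and adjusted p = 0.0366 with an estimated correlation). The median was again 2.32 with Hspa1a, which had no control count, set at its bound of at least 24.4-fold against a floor of 3 counts over the control group. Hspb8 rose 16.1-fold, Hsph1 13.9-fold and Dnaja1 5.32-fold. All 31 tested genes of the proteasome subunit list rose, with a median of 0.68 (camera adjusted p = 7.2e-10), including Psmd11 (1.42 ± 0.05), Psmc6 (1.26 ± 0.05), Psma5 (1.24 ± 0.05) and Psmd8 (1.09 ± 0.05). Chaperone genes of the endoplasmic reticulum moved less, with 19 of 28 higher, 3 lower and 6 not past the test, and a median of 0.32 (camera adjusted p = 0.0071, and adjusted p = 0.168 with an estimated correlation). Hspa5, the gene of the chaperone BiP, rose 2.65-fold and Dnajb9 3.15-fold, with Herpud1 at 0.95 ± 0.05 and Canx at 0.78 ± 0.04.

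Autophagy genes rose on balance. Of 37 tested, 25 rose, 5 fell and 7 did not pass, and 26 rose and 5 fell adjusted over the list alone, with a median of 0.45 (camera adjusted p = 6.0e-05). The cargo receptor genes Sqstm1 and Nbr1 (0.81 ± 0.04) rose, as did Gabarapl1 (2.54 ± 0.06), an ATG8 family gene, and the mitophagy receptor gene Bnip3 (1.51 ± 0.07). Lysosomal genes also had 25 of 37 higher, 5 lower and 7 not past the test, or 25 higher and 7 lower adjusted over the list alone. Their median was 0.34 (camera adjusted p = 0.0029, and adjusted p = 0.319 with an estimated correlation). The proton pump subunit gene Atp6v1b2 rose 2.72-fold, the cholesterol transporter gene Npc1 2.20-fold, and the cathepsin genes Ctsl and Ctsd 1.94-fold and 1.73-fold.

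Stress signalling lists were higher on balance, with members in both directions. Of 33 tested ATF4 targets of the integrated stress response, 20 rose, 9 fell and 4 did not pass, with a median of 0.48 (camera adjusted p = 9.0e-09). Ppp1r15a and Ddit3, which act in recovery from and death under this stress, rose 12.4-fold and 7.05-fold. Slc7a11 and Gdf15, the members with the smallest p, are also in the NRF2 and p53 lists, respectively. Among the 9 lower, named after their values were seen, were Pck2 (−1.19 ± 0.06), Aldh1l2 (−0.97 ± 0.05), Atf5 (−0.49 ± 0.05), Asns (−0.38 ± 0.04) and Psat1 (−0.22 ± 0.05). The p53 target list had 21 of 29 higher, 4 lower and 4 not past the test, or 21 higher and 5 lower adjusted over the list alone (median 0.79, camera adjusted p = 2.6e-11). Gadd45a rose 21.1-fold, the cell cycle inhibitor gene Cdkn1a 4.36-fold and Mdm2, the gene of the ligase that degrades p53, 3.22-fold. Immediate early genes numbered 23 higher, 5 lower and 1 not past the test (median 1.45, camera adjusted p = 6.8e-19, and adjusted p = 0.0366 with an estimated correlation). Among them Fosl1 rose 17.3-fold, Dusp5 24.8-fold, Maff 8.83-fold and Jun 5.70-fold. Of 17 senescence-associated genes 8 rose, 6 fell and 3 did not pass, with a median of 0.22 (camera adjusted p = 0.0204, and adjusted p = 0.111 with an estimated correlation), or 0.03 under total counts alone, and this call also ended with limma-voom (adjusted p = 0.513, the highest of a range from 4.4e-05 over all alternatives). Its members with the smallest p were Gdf15, Cdkn1a and the chemokine genes Cxcl1 and Ccl2.

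Proliferation genes were lower with CSE. All but 1 of 37 tested mitosis genes were lower and none was higher, with a median of −1.02 (camera adjusted p = 9.2e-15, and adjusted p = 0.111 with an estimated correlation). Top2a, the DNA topoisomerase gene of dividing cells, fell from 202 ± 3.55 to 59.4 ± 3.93 CPM, and Cdc20, Cenpf and Kif20a were at −1.70 ± 0.06, −1.61 ± 0.06 and −1.43 ± 0.06. For S phase, 31 of 37 genes fell, 4 rose and 2 did not pass, with a median of −0.80 (camera adjusted p = 4.0e-06, and adjusted p = 0.0851 with an estimated correlation). The replication helicase genes Mcm2 and Mcm7 were at −1.62 ± 0.07 and −1.28 ± 0.06, the polymerase gene Pold1 at −1.94 ± 0.09, and the ribonucleotide reductase gene Rrm2 at −1.33 ± 0.08.

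**Figure D3:**
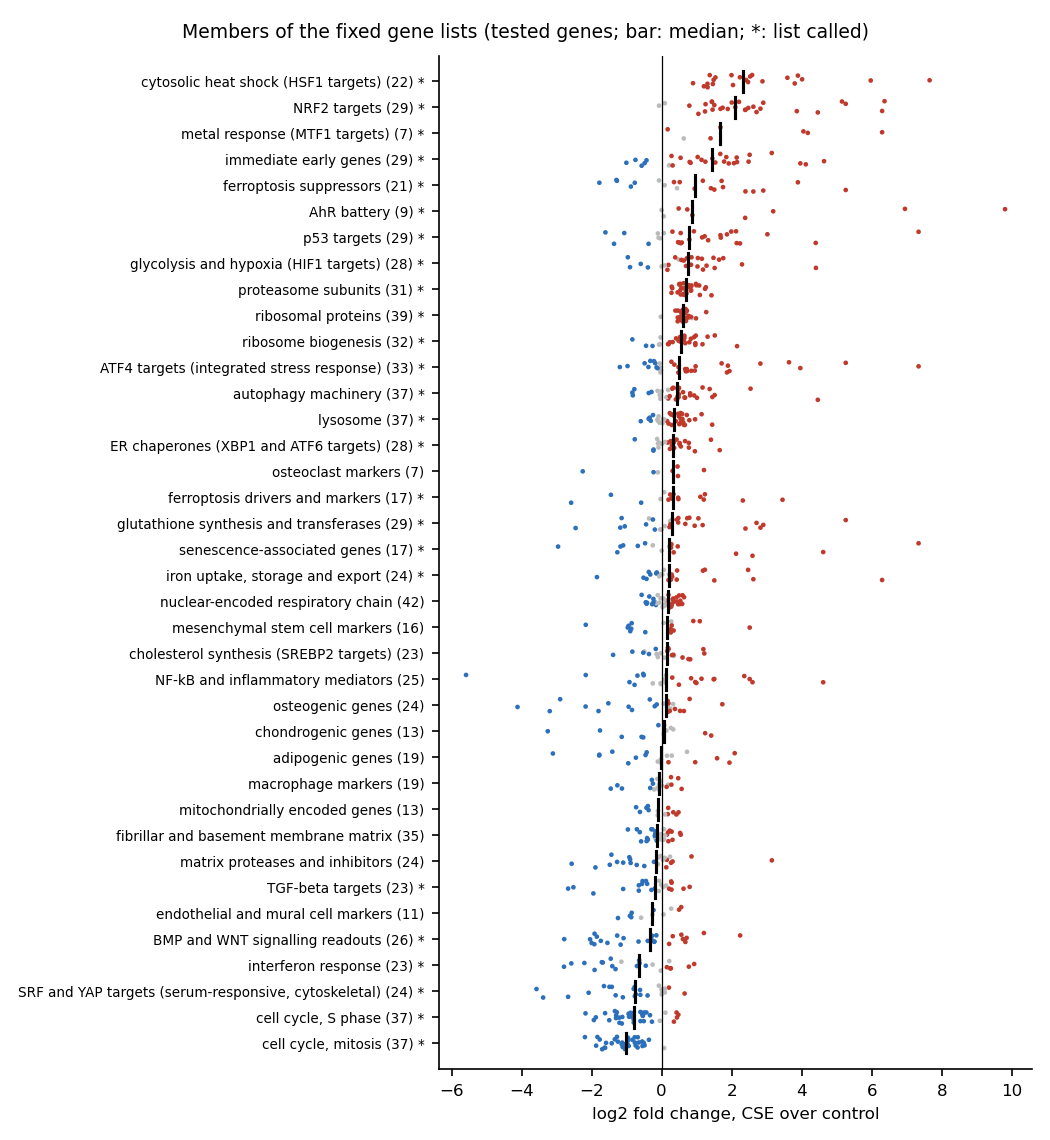
Log2 fold changes of CSE over control (x axis) of the tested members of 38 fixed gene lists (rows, number of tested members in parentheses), with red points for members called higher, blue for lower, grey for not called, and a black bar at the list median. Lists marked with an asterisk passed the camera test, from cytosolic heat shock with a median of 2.32 to mitosis with a median of −1.02.

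Genes of the bone, cartilage and fat lineages moved in both directions, and Sp7, Sox9 and Vdr were among the deepest falls. Sp7, which encodes osterix and is required for osteoblast formation, fell from 28.5 ± 1.79 to 1.64 ± 0.114 CPM. The vitamin D receptor gene Vdr fell from 45.7 ± 2.03 to 4.98 ± 0.155 CPM, the homeobox gene Dlx5 from 21.4 ± 0.183 to 4.73 ± 0.767 CPM and the BMP receptor gene Bmpr2 from 327 ± 21.1 to 170.2 ± 9.50 CPM. Of 24 tested osteogenic genes 9 rose, 11 fell and 4 did not pass. The list did not pass (camera adjusted p = 0.152), and its median of 0.11 and mean of −0.52 differ in sign. Fry called it lower (adjusted p = 6.2e-05), but fry called 35 of 38 lists and so says little about this one. Of genes chosen after their values were seen, Runx2, which acts upstream of Sp7, was higher (0.38 ± 0.06) and so was Bmp2 (1.73 ± 0.14), whereas Bmp4 (−2.90 ± 0.29) and the collagen gene Col1a1 (−0.14 ± 0.04, 28797 CPM in the control) were lower. Of 13 chondrogenic genes 2 rose, 6 fell and 5 did not pass, or 2 and 5 adjusted over the list alone, with a median of 0.06, a mean of −0.29 and no call (camera adjusted p = 0.171, lower with fry at adjusted p = 7.4e-05). Sox9, the master regulator gene of cartilage, fell from 40.9 ± 0.713 to 4.26 ± 0.592 CPM. Sox6 (−1.76 ± 0.23), Cilp (−0.57 ± 0.10) and the aggrecan gene Acan (−0.53 ± 0.05) were lower too. Of 19 adipogenic genes 5 rose, 8 fell and 6 did not pass (median −0.03, camera adjusted p = 0.791). Here the lipid droplet gene Plin2 (2.08 ± 0.06) and Cebpa (1.58 ± 0.07) rose, while Scd and the lipoprotein lipase gene Lpl (−0.95 ± 0.06) fell.

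**Figure D4:**
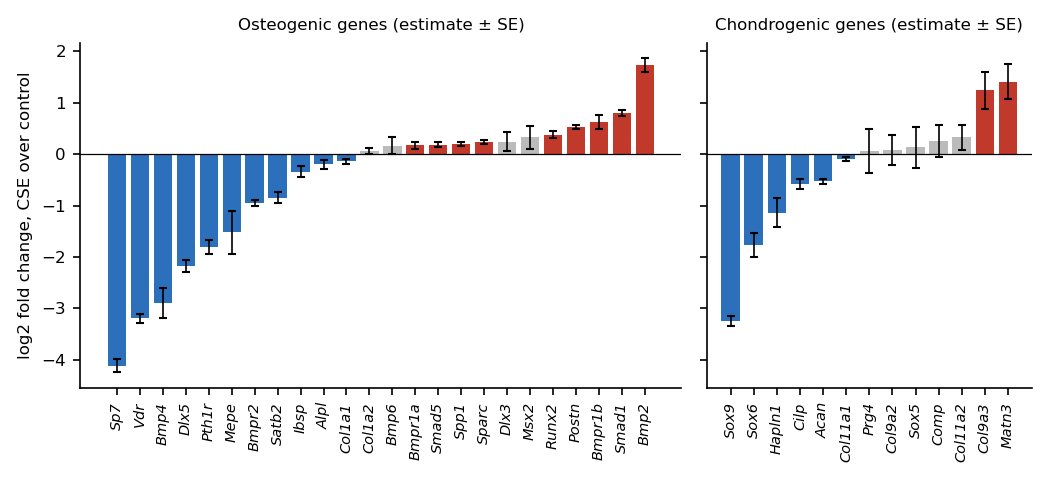
Log2 fold change of CSE over control (y axis, bars, with SE as error bars) for the 24 tested osteogenic genes (left) and 13 tested chondrogenic genes (right), red for called higher, blue for called lower and grey for not called. Sp7 at −4.12 and Sox9 at −3.25 are the lowest of their lists, and Bmp2 at 1.73 is the highest osteogenic gene.

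Signalling genes of skeletal development were lower on balance. Of 26 BMP and WNT readouts 8 rose and 18 fell, with a median of −0.34 (camera adjusted p = 0.0011, and adjusted p = 0.0564 with an estimated correlation). The WNT receptor gene Fzd1 was at −1.74 ± 0.05. The BMP antagonist gene Grem1 fell from 424 ± 22.4 to 111.9 ± 8.32 CPM, and Nkd2, which encodes a WNT inhibitor, was at −1.92 ± 0.07. Among 23 TGF-beta targets, 6 rose, 12 fell and 5 did not pass (median −0.20, camera adjusted p = 0.0020, and adjusted p = 0.116 with an estimated correlation), including the ligand genes Tgfb3 (−2.52 ± 0.05) and Tgfb2 (−1.95 ± 0.05). SRF and YAP targets, which respond to serum and cytoskeletal tension, had 16 of 24 lower, 2 higher and 6 not past the test (median −0.75, camera adjusted p = 2.0e-09, and adjusted p = 0.111 with an estimated correlation). Thbs1 fell from 13083 ± 345 to 1253 ± 23.3 CPM and Ctgf from 5683 ± 76.5 to 892 ± 105 CPM, with Crim1 (−1.49 ± 0.05) and Amotl2 (−1.65 ± 0.05) also lower.

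Structural matrix genes changed by small amounts, and neither matrix list passed camera with TMM scaling and filterByExpr. Of 35 fibrillar and basement membrane genes 8 rose, 17 fell and 10 did not pass, none by 2-fold or more (median −0.13, camera adjusted p = 0.260, lower with fry at adjusted p = 0.0076). Thbs2 (−0.96 ± 0.04), Col8a1 (−0.71 ± 0.05), Col12a1 (−0.62 ± 0.05) and Tnc (−0.59 ± 0.04) were lower. Of 24 matrix proteases and inhibitors 6 rose, 12 fell and 6 did not pass (median −0.16, camera adjusted p = 0.0697). The list passed camera with no filter on low counts (adjusted p = 0.0223), under upper-quartile scaling (adjusted p = 0.0363) and under total counts alone (adjusted p = 0.0312). It also passed with fry (adjusted p = 4.0e-05), which called 35 of 38 lists, within a range of 4.0e-05 to 0.170 over all alternatives. The urokinase receptor gene Plaur rose 8.85-fold, whereas the aggrecanase genes Adamts1 (−1.27 ± 0.05) and Adamts5 (−2.57 ± 0.11) were lower.

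Genes of glycolysis and hypoxia (HIF1 targets) rose in 21 of 28 cases, with 4 lower and 3 not past the test (median 0.74, camera adjusted p = 8.0e-09, and adjusted p = 0.0874 with an estimated correlation). The peptide hormone gene Adm rose 21.2-fold, the glucose transporter gene Slc2a1 4.90-fold, Ero1l 3.38-fold and the hexokinase gene Hk1 2.43-fold. Ribosomal protein genes rose in 37 of 39 cases, with 2 not past the test (median 0.62, camera adjusted p = 1.4e-06, and adjusted p = 0.168 with an estimated correlation), for example Rpl12 (0.98 ± 0.05), Rpl13a (0.68 ± 0.05), Rps7 (0.65 ± 0.05) and Rpl7 (0.62 ± 0.04). Ribosome biogenesis genes rose in 26 of 32 cases, with 3 lower and 3 not past the test (median 0.56, camera adjusted p = 1.4e-05, and adjusted p = 0.115 with an estimated correlation). Myc rose 4.44-fold, and the nucleolar protein genes Gnl3, Wdr43 and Nolc1 rose 2.86-fold, 2.48-fold and 1.95-fold. Nuclear-encoded respiratory chain genes had 21 of 42 higher, 10 lower and 11 not past the test (median 0.19, camera adjusted p = 0.521, higher with fry at adjusted p = 0.0264), with Cox5a (0.64 ± 0.05), Cox4i1 (0.59 ± 0.06), Ndufa4 (0.53 ± 0.05) and Cox6c (0.50 ± 0.05) higher. The 13 mitochondrially encoded genes were divided into 5 higher, 5 lower and 3 not past the test (median −0.11, camera adjusted p = 0.925). ND1 fell by 0.62, whereas COX3, COX1 and CYTB rose by 0.48, 0.42 and 0.33. Cholesterol synthesis genes had 10 of 23 higher, 5 lower and 8 not past the test (median 0.15, camera adjusted p = 0.461, higher with fry at adjusted p = 0.0024), with Insig1 (1.19 ± 0.09) higher and Dhcr7 (−1.39 ± 0.12) lower.

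Inflammatory genes split, and more interferon response genes were lower than higher. Cxcl1 and Ccl2, chemokine genes for neutrophils and monocytes, rose 24.4-fold and 6.03-fold, and the mitochondrial superoxide dismutase gene Sod2 1.99-fold. Cxcl12, the stem cell retention factor gene of marrow stroma, fell from 378 ± 12.1 to 84.0 ± 5.80 CPM. Of 25 tested genes of NF-kB and inflammation 12 rose, 7 fell and 6 did not pass (median 0.12, camera adjusted p = 0.402, higher with fry at adjusted p = 7.3e-04). The interferon list had 13 of 23 lower, 5 higher and 5 not past the test (median −0.64, camera adjusted p = 0.0231, and adjusted p = 0.248 with an estimated correlation), with Oasl2 at −2.79 ± 0.17, Ifit2 at −1.45 ± 0.09 and Parp14 at −1.41 ± 0.09.

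None of the cell type marker lists tested with camera was called. Fry, which called 35 of 38 lists, called the mesenchymal stem cell (adjusted p = 7.9e-05), macrophage (adjusted p = 0.0042) and endothelial and mural (adjusted p = 0.0016) markers lower. Of 16 tested mesenchymal stem cell markers 7 rose, 7 fell and 2 did not pass, with a median of 0.16 and a mean of −0.07 (camera adjusted p = 0.188). Cd44 rose 2.13-fold, whereas Pdgfrb (−0.87 ± 0.05), Prrx1 (−0.95 ± 0.05) and Cxcl12 fell. Macrophage transcripts were present in both groups, with Lyz2 at 1414 ± 24.8 CPM with CSE and 1175 ± 19.3 in the control. Of 19 macrophage markers 5 rose, 6 fell and 8 did not pass, or 4 and 6 adjusted over the list alone (median −0.08, camera adjusted p = 0.485). Laptm5 was higher (0.57 ± 0.05) and the scavenger receptor gene Msr1 (−1.26 ± 0.07) and Cd14 (−1.45 ± 0.08) were lower, and the call of Lyz2 did not hold under total counts alone (0.08, edgeR adjusted p = 0.0734, the highest of a range from 2.0e-12 over all alternatives). Only 2 of 23 neutrophil, lymphoid and erythroid markers passed the filter on low counts, of which Pf4 was at 0.43 ± 0.15 (edgeR adjusted p = 0.0126) and lost its call without CSE replicate 2 (0.30) or without control replicate 2 (0.37), under upper-quartile scaling (0.30) and under total counts alone (0.25). Of 11 endothelial and mural markers 2 rose, 5 fell and 4 did not pass (median −0.26, camera adjusted p = 0.251), with Myh11 (−1.25 ± 0.05) and Cspg4 (−0.86 ± 0.05) lower and Abcc9 (0.50 ± 0.08) and Egfl7 (0.56 ± 0.09) higher. Of 7 osteoclast markers 4 rose, 2 fell and 1 did not pass, or 4 and 3 adjusted over the list alone, with a median of 0.31 and a mean of −0.02 (camera adjusted p = 0.986). The RANK gene Tnfrsf11a fell by 2.25, while Acp5, Oscar and Mmp9 rose by 0.45, 1.21 and 0.31, the last without a call under total counts alone (0.12, edgeR adjusted p = 0.0713, the highest of a range from 2.0e-05 over all alternatives).

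Across all 38 tested lists, 19 were called higher and 6 lower. These calls are not independent, because lists share members. Slc7a11 is in the NRF2, glutathione, ferroptosis suppressor and ATF4 lists, and Hmox1 in the NRF2, iron and metal response lists. Nqo1 and Sqstm1 of the NRF2 list are also in the aryl hydrocarbon receptor and autophagy lists, respectively. With an estimated correlation 11 lists remained higher, those of NRF2 targets, the aryl hydrocarbon receptor battery, glutathione, ferroptosis suppressors, autophagy, ATF4 targets, heat shock, the metal response, p53 targets, immediate early genes and proteasome subunits, and none remained lower. The camera adjusted p of these 11 lists then lay between 0.0279 (NRF2 targets) and 0.0462 (ATF4 targets), far above the values with the preset correlation. Among lists that lost their call, the estimate was below the preset 0.01 for ferroptosis drivers (−0.026), iron (−0.0249), senescence (−0.0215) and BMP and WNT (−0.0168). For the other lists that lost their call it was above 0.01. A higher correlation therefore does not account for the lost calls of those with an estimate below 0.01, whose cause was not tested.

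**Figure D5:**
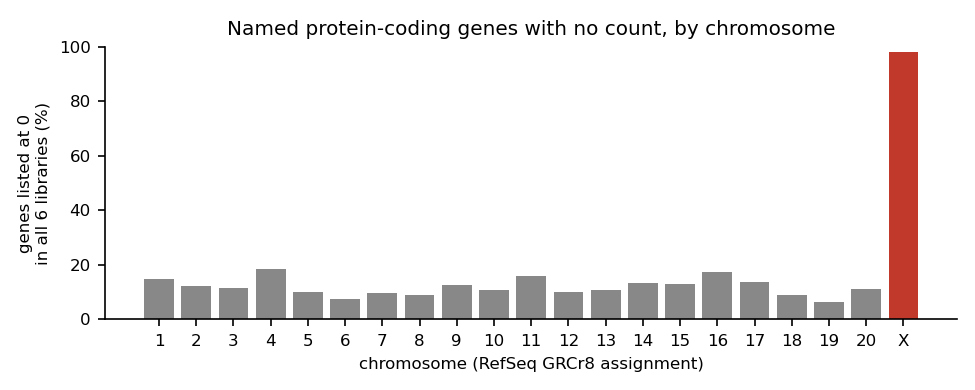
Share of named protein-coding genes listed at 0 in all 6 libraries (y axis, percent) for each chromosome to which the RefSeq table of GRCr8 assigns them (x axis, 1 bar per chromosome). Chromosome X stands at 98.1%, and the autosomes lie between 6.28% and 18.2%.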

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

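The runs with all libraries thinned to the smallest total and without the mitochondrially encoded genes were chosen after seeing the data; all other alternatives were planned. Between 4736 and 4864 genes were higher and between 4801 and 4950 lower when any 1 library was left out, with 94.1% to 95.8% of the called genes shared. DESeq2 gave 4791 higher and 4641 lower, no filter on low counts 5366 and 5318, thinning 4791 and 4935, and leaving out the mitochondrially encoded genes 4869 and 5022. Total counts alone gave 3749 higher and 6319 lower, shared 88.7% of the calls, the lowest share of any alternative, and turned the direction of 1 gene called in both, while upper-quartile scaling gave 4045 higher and 5990 lower. The F test with a replicate block gave 4821 higher and 4935 lower and shared 9711 calls. Libraries with the same number did not resemble each other more than other pairs (correlations of deviations from the group mean across genes of 0.02, −0.03 and 9.4e-04, other pairs −0.08 to 0.09). No shared deviation by number was therefore seen, but this cannot settle whether the numbers pair the samples, which the labels do not say. The test against a 2-fold change left 1036 genes higher and 1252 lower, a stricter question than a size filter. With an estimated correlation 11 lists were called higher and 0 lower, and fry, which does not compare a list with other genes, called 22 higher and 13 lower. limma-voom called 17 higher and 6 lower, without the iron and senescence lists. Gpx4, not called, was at −0.052 with upper-quartile scaling and −0.104 with total counts alone, which is the shift of all genes by −0.137 and −0.188 and no evidence about this gene. The test direction of the mitochondrially encoded genes turned with limma-voom (median −0.093), with quality weights (−0.074) and without control replicate 1 (0.06), and their median ranged from −0.12 to 0.11 with 1 library left out. That of the osteoclast markers turned with limma-voom (median 0.31), quality weights (0.31), the replicate block (0.31) and fry (0.31), and for both lists the cause was not tested. Over all alternatives, values of named genes kept their direction and side of the threshold 2874 times, lost a call 8 times and turned 2 times, and lists did so 721 times, lost a call 18 times, gained a call 13 times and turned 7 times. Camera was not rerun for the robust fit, which it does not use. Depth limits the ratio of Cyp1a1, which rests on 3 control counts.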

Other observations

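The test of serum, the test of cytotoxic lymphocytes by granule partners and both tests of chromosome X were chosen after the result was seen, and the symbol families were chosen after the gene-level results but before their own. Members of families, marker sets and chromosome X that are named were chosen after their values were seen. Gene families that share a symbol stem and hold 10 or more tested genes were tested with camera, 132 in all, of which 9 were called higher, 3 lower and 0 with an estimated correlation. That estimate was below the preset 0.01 for Psmd (0.0027), Adamts (−0.0764) and Kdm (−0.0392), and above it for the other called families. A higher correlation therefore does not account for the lost calls of Psmd, Adamts and Kdm, whose cause was not tested. Of 13 Adamts genes, which encode secreted metalloproteases, 9 fell, none rose and 4 did not pass (median −1.12, camera adjusted p = 4.8e-04, and adjusted p = 0.550 with an estimated correlation), with Adamts6 at −2.53 ± 0.08 and Adamts9 at −1.44 ± 0.09. Of 30 kinesin (Kif) genes 20 fell, 4 rose and 6 did not pass (median −0.60, camera adjusted p = 0.0016, and adjusted p = 0.611 with an estimated correlation), including Kif26b (−2.88 ± 0.10), which is outside the mitosis list, and Kif14 (−2.77 ± 0.11). Genes of the Arhgef family fell in 10 of 17 cases and rose in 5, with 2 not past the test (median −0.76, camera adjusted p = 0.0190, and adjusted p = 0.611 with an estimated correlation), with Arhgef40 at −2.44 ± 0.07.

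Deubiquitinase genes of the Usp family rose in 29 of 41 cases and fell in 8, with 4 not past the test (median 0.47, camera adjusted p = 0.0113, and adjusted p = 0.611 with an estimated correlation), among them Usp32 (1.64 ± 0.07) and Usp14 (1.19 ± 0.06), which acts at the proteasome. Histone demethylase genes (Kdm) rose in 12 of 13 cases with 1 not past the test (median 0.29, camera adjusted p = 0.0434, and adjusted p = 0.611 with an estimated correlation), led by Kdm3a (1.64 ± 0.06), Kdm2a (1.14 ± 0.05) and Kdm6b (1.09 ± 0.06). Subunit genes of the chaperonin that folds actin and tubulin (Cct) rose in 9 of 11 cases with 2 not past the test (median 0.68, camera adjusted p = 0.0195, and adjusted p = 0.611 with an estimated correlation). Genes with the symbol stem Eif, which covers translation initiation factors and some of their regulators, rose in 37 of 53 cases and fell in 8, with 8 not past the test (median 0.44, camera adjusted p = 0.0195, and adjusted p = 0.660 with an estimated correlation), with Eif5 at 1.37 ± 0.05 and Eif1 at 1.15 ± 0.05. The families were not refitted under the scaling alternatives, which moved all genes by −0.14 with upper-quartile scaling and −0.19 with total counts alone.

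Granzyme B family transcripts, which belong to cytotoxic lymphocytes and mast cells, were higher with CSE, with 8155 counts of Gzmb against 64 and a family sum of 192 ± 11.7 CPM against 3.88 ± 1.28. The rise came from Gzmb, Gzmbl2 (664 counts against 28) and Gzmbl3 (2470 against 121). Gzmbl1, Gzmf and Gzmn had 0 counts in both groups, and Gzmc had 2 against 0. Reads moved between near-identical copies are argued against, since the lowest family sum with CSE was 33.3 times the highest in the control, and mast cells are argued against by 10 marker genes that together reached 0.194% of the CPM of Gzmb. For lymphocytes, the planned test on the sum of 16 marker genes decided nothing, because the sum reached 3.17% of the CPM of Gzmb, between the planned bounds of 1% and 10%, and 1.44 times its control level. In the test that replaced it, the granule partner genes Prf1, Nkg7 and Gzma had 0 counts with CSE. That allows up to 0.0368% of the counts of Gzmb. These partners were picked from the same 16 markers after the planned result. Their counts therefore show only that their own transcripts were not detected with CSE, and decide nothing about lymphocytes as a source. Among the other markers Gzmm had 43 counts with CSE against 11 and Faslg 77 against 29. Transcription of the family in the cultured cells under CSE may be a hypothesis to follow, found and tested on the same data. Lymphocytes and other cells that express Gzmb stay open as a source.

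Immediate early genes rose with CSE while SRF and YAP targets were lower, and the sources used here do not say whether the extract was given in serum. The test assumed that serum alone would raise both groups, which no serum control at 6 h was there to show. Of the 24 SRF and YAP targets 16 were lower and 2 higher, with a median of −0.75 (camera adjusted p = 0.111 with an estimated correlation). For the rise of the immediate early genes, serum stays open, alone or together with an effect of the extract on those targets. It cannot be told apart from a response to CSE, because both would act in the same libraries.

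Genes of chromosome X were listed at 0 for 563 of 574 named protein-coding genes, 98.1%, against 6.28% to 18.2% on the autosomes. Low expression is argued against by 10 of 10 genes that nearly every cell uses, among them Hprt1, Pgk1 and Ddx3x, which were at 0 in all 6 libraries. The share is consistent with reads of this chromosome not having been counted upstream. No other explanation was tested. This leaves members of the fixed lists unmeasured, among them Acsl4, Lamp2, Tfe3, Phex, Bgn and Timp1.

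In the 10 splits of the 6 libraries into 3 and 3, the real one called 9894 genes and the highest other 0, so 1 split reached the real count, and 10 splits are too few for a share under 0.05. For a general loss of short-lived transcripts, 220 zinc finger (Zfp) genes had a median of 0.10, against a bound of −0.1 or more for no such loss, written before this value was seen, but with 91 higher, 73 lower and 56 not past the test, values centred by the scaling and a shift of −0.19 under total counts alone, this median decides nothing.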
